A study of Homo sapiens with 4 samples.

How the data were processed

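Poly-A RNA was sequenced from primary human prostatic fibroblasts grown from non-cancerous prostate tissue, serum starved and kept for 6 h with vehicle or with 20 µg/ml of large oncosomes, very large membrane vesicles shed by cancer cells, here from the prostate cancer cell line 22Rv1. There were 2 libraries with vehicle, called control 1 and control 2, and 2 with large oncosomes, all made with a stranded kit per the labels' protocols. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

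The deposited files give 1 value for each of 25275 rows, each with a gene name and a genomic interval. The unit was not written in the files and was read as FPKM (fragments per kilobase, scaled to sequencing depth) from the deposited columns, which have the layout that Cufflinks writes, and from the values, which are not whole and sum to between 404697 and 421532 per library. The submitters' processing notes list Bowtie 1.1.1, RSEM 1.2.20 and the genome build GRCh38, with no role for each. The intervals in the files are not those of GRCh38: of 20871 names also found in a GRCh38 annotation, 13.3% lie on an overlapping interval there. Coordinates are therefore given as in the files, on a build that is not given in the sources used here. The total number of fragments is not stated. In control 1 the values of short single-exon olfactory receptor genes fell at whole multiples of a common step for 18 of 24 rows, within 0.1 of a whole number, which would correspond to a depth of about 3.86e+07 fragments. The step was taken from the same rows, as the median of a band of their values, so the match behind this estimate was partly built in. No such estimate was made for the other 3 libraries, whose depth is unknown, so no counting interval is given.

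The name and interval columns are the same, in the same order, in all 4 files, but the values do not follow them in 3 of the files. Olfactory receptor genes, which fibroblasts do not use, had 0 of 377 rows at 1 FPKM or more in control 1, against 32 in control 2 and 35 and 36 in the large oncosome libraries. Ribosomal protein genes had 76 of 81 rows at 50 FPKM or more in control 1, against 33, 32 and 34. Names were therefore taken to hold in control 1, and not in general in the other 3 libraries. No value was moved to another name for the tests over all rows or over rows with checked names. In the step on abundant genes below, a gene is given the highest value of its stretch of rows, which for 14 of 15 genes stood on another row in at least 1 library and may belong to another gene.

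The test fixed before the data were examined was limma's moderated test with a mean-variance trend and robust empirical Bayes on log2(FPKM + 1), for rows with at least 1 FPKM in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided and without a replicate block. It was run on all rows as deposited. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low values. The 24 gene lists were fixed at the same time (610 of 623 entries were found by name or by a synonym, and 1 list, the mitochondrially encoded genes, had no member in the files), and 23 lists with at least 5 tested rows went through camera with a preset correlation of 0.01. The genes named were also fixed by rule: MYC, AKT1, ACTA2, IL6, MMP9 and THBS1; the 10 largest rises and falls among called genes or, where fewer than 5 were called in a direction, the 10 genes with the smallest p in it; and from each list up to 4 called members or the tested member with the smallest p. The last parts of the rule were applied to rows with checked names (below). Genes named from control 1 alone, from the abundant genes below or as examples of misplaced rows were chosen after their values were seen. Y-linked genes and XIST are not reported, and some members of the lists are not reported singly here.

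Further steps were chosen after seeing the data. A row's name was called checked where the 2 nearest rows on each side with at least 1 FPKM lay within 2-fold of control 1 in each other library (0.1 added to both values), without looking at the row's own values, and where the name was on 1 primary chromosome and occurred once. This setting was picked from 48 combinations of 4 expression thresholds, 4 tolerances and 3 numbers of neighbours, judged by how well the 2 controls agreed and how many rows remained, and calls between the groups for 1, 2 and 3 neighbours were seen at about the time of the choice. It left 922 rows, of which 517 were tested. At 6 of these (1.16%) the controls still differed over 2-fold. The test was repeated on these rows alone. Second, abundant genes were followed as the highest value of their stretch of rows: a gene had to exceed every row within 150 rows on each side 2-fold in control 1, and the highest value within 75 rows was taken in each library if it was also the highest within 150 rows and exceeded the next one 1.5-fold. This rule was reached after 5 pairs of window sizes and earlier versions that did not ask for the same maximum in both windows, and was tightened after values of FTH1, ANXA5 and RPS2 between the groups had been seen. Of 17 genes, 15 passed, and these were tested with limma without a trend.

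The scripts were tested on simulated data: control 1 with added noise (SD 0.12 on the log2 scale) in 4 libraries. In 3 of them 8% of rows were drawn and moved by a random number of rows, which also shifted the rows they passed. That share was picked from 4 so that about as many rows passed the name check as in the real data. Over 3 simulations, 13.2% to 16.8% of all tested rows then held their own values in all 4 libraries. Over the rows tested the simulated controls correlated with r between 0.43 and 0.48. In the files r was 0.56, but over all rows, including those not tested, so these values are not directly comparable. Between 91.3% and 94.5% of the rows that passed held their own values in 3 simulations. With 1500 changed rows drawn, 483 checked rows were tested and 47 called, 2 of them not changed, and 89.5% of the 19 rows changed 1.5-fold were recovered. With 200 changed rows drawn, 672 checked rows held 4 changed ones, of which 3 were called. With no changed row, 1 of 499 checked rows was called. The same test over all rows called 0, 423 and 709 rows that had not been changed in the simulations with 200, 1500 and 0 changed rows. Displacement was drawn separately for each simulated library. In the files, the maximum taken for RPS15A stood on the same other row in both large oncosome libraries. The simulations therefore do not measure false calls from a misplacement shared by both libraries of a group.

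The alternatives tried were leaving out each library, a replicate block, quantile normalization, median centring, no filter on low values, a filter of 3 FPKM, empirical Bayes without the robust option, a pseudocount of 0.1, a minimum change of 1.5-fold, camera with an estimated correlation, fry, and other settings of the 2 rules chosen later. Count-based tests, planned only for counts, were not run because the values are FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.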

Results

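Gene expression was measured in primary human prostatic fibroblasts after 6 h with vehicle or with 20 µg/ml of large oncosomes from 22Rv1 prostate cancer cells, with 2 libraries in each group. The 4 libraries were alike in their overall distribution: 11904 to 11945 rows had at least 1 FPKM, and the sums ran from 404697 to 421532 FPKM. The question the labels pose is which fibroblast transcripts differ after exposure to the vesicles. It can be answered for a small part of the genes only, because the values of control 2 and of both large oncosome libraries are out of step with the gene names at many rows. Of 13392 tested rows, 517 had names that passed the check on neighbouring rows.

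In control 1, where the names were taken to hold, fibroblast genes were abundant. The iron storage genes FTH1 and FTL (10402 and 6824 FPKM), the protease inhibitor TIMP1 (7085 FPKM) and the actin-binding TMSB10 (4467 FPKM) were the most abundant transcripts. Of 17 fibroblast identity genes, 16 had at least 1 FPKM, with a median of 44.4 FPKM over the list, among them the collagens COL1A1 (2560 FPKM) and COL1A2 (1633 FPKM), VIM (1858 FPKM), THY1 (522.8 FPKM) and DCN (518 FPKM). Collagen and matrix genes had a median of 144 FPKM and 27 of 30 at 1 FPKM or more, although FN1, encoding fibronectin, was listed at 0, which can be a failed estimate. Contractile and TGF-beta genes had a median of 52.2 FPKM, with TPM2 at 2085, TAGLN at 1156 and TGFBI at 912 FPKM. Epithelial, endothelial and immune markers were low. In the prostate luminal and cancer epithelial list 8 of 31 genes reached 1 FPKM, the highest being KRT19 (99.8 FPKM) and KRT18 (37.2 FPKM), and KLK3, encoding prostate-specific antigen, was listed at 0. Of the endothelial and immune markers 2 of 13 and 2 of 17 reached 1 FPKM, led by EGFL7 (12.8 FPKM) and CD68 (69.4 FPKM), and 3 of 10 basal epithelial genes did. Smooth muscle genes had a median of 8.51 FPKM, with 6 of 11 at 1 FPKM or more, led by ACTG2 (73.1 FPKM), SYNPO2 (30.5), CNN1 (24.0) and SMTN (22.1), of which ACTG2 and CNN1 are also in the contractile list.

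Growth and stress genes were also measured in this library. MYC target and ribosome biogenesis genes had a median of 8.48 FPKM (58 of 61 at 1 FPKM or more), with NPM1 at 426 and NCL at 197 FPKM. All 46 cytosolic ribosomal protein genes exceeded 10 FPKM, with a median of 669 FPKM. Cell cycle genes had a median of 3.32 FPKM, although CCND1, encoding cyclin D1, stood at 639.9 FPKM, and among p53 targets (median 21.5 FPKM) the cell cycle inhibitor CDKN1A stood at 402 FPKM. Median levels were 50.2 FPKM for NRF2 and metallothionein genes, 58.0 for heat shock, 41.9 for cholesterol and fatty acid synthesis, 33.6 for unfolded protein and amino acid stress, 32.7 for glycolysis and hypoxia, and 22.0 for matrix proteases and their inhibitors. They were 8.64 FPKM for FOXO and growth factor withdrawal genes, 6.40 for immediate early and ERK feedback, 6.22 for secreted growth factors, 3.39 for NF-kB and inflammatory and 3.33 for interferon response genes. CCL2, a monocyte chemokine, stood out in the inflammatory list at 440.5 FPKM. These levels come from 1 library and have no replicate error.

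**Figure D1:**
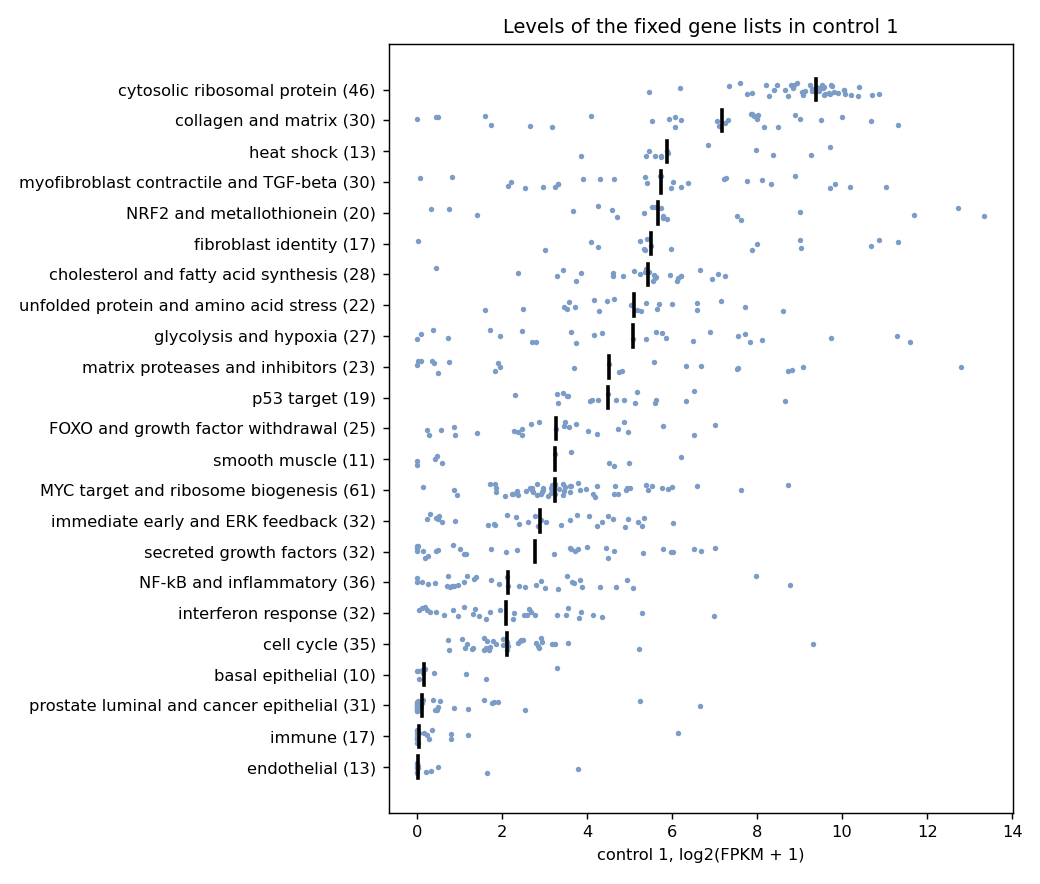
Each point is a gene of a list fixed in advance, placed by its level in control 1 as log2(FPKM + 1), with the number of genes in parentheses and a black bar at the list's median. The ribosomal protein list is the highest, with a median of 669 FPKM, and the endothelial, immune, luminal and basal epithelial lists lie near 0.

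The order of the values was compared between libraries. At the same row, control 1 and control 2 correlated with r = 0.56 over all rows on the log2(FPKM + 1) scale, no better than control 1 with the large oncosome libraries (0.55 and 0.56), and 55.6% of rows at 10 FPKM or more in either control differed over 2-fold between the controls. The most abundant value stood on FTH1 in control 1 and on DRAP1, NEU3 and EHD1 in the others. Of values at 200 FPKM or more in control 1 that were over 2-fold off at the same row, 94.1%, 92.9% and 76.5% were matched within 1.2-fold by a value within 100 rows in control 2 and the 2 large oncosome libraries, against 33.5% to 36.6% in distant stretches of rows. At the 517 rows whose names passed the neighbour check the libraries correlated with r between 0.97 and 0.98. Rows are not independent replicates, and these correlations only describe the files.

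**Figure D2:**
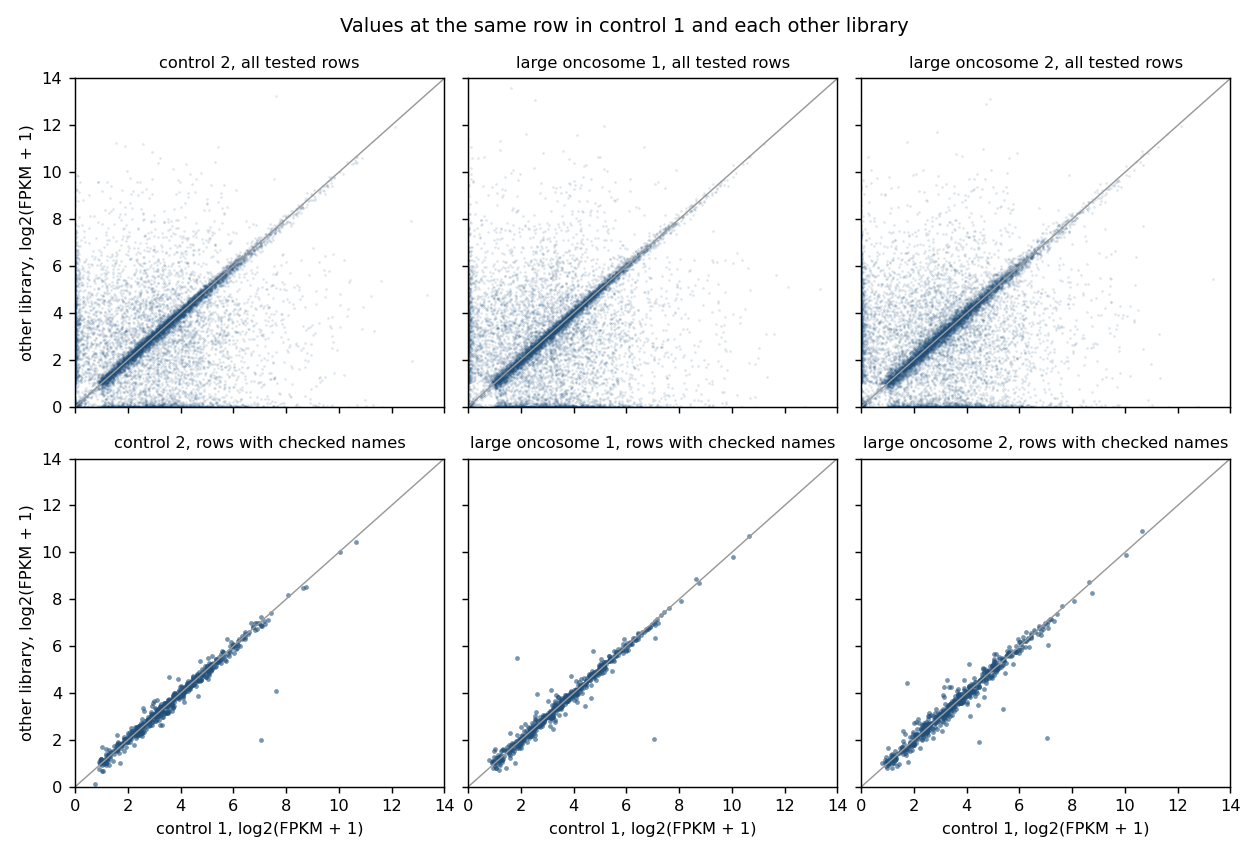
Each point is a row, placed by its value in control 1 (horizontal axis) and in 1 other library (vertical axis), both as log2(FPKM + 1), with the line of equality in grey. In the upper panels, with all tested rows, many points lie far from the line; in the lower panels, with the 517 rows whose names were checked, most lie along it.

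The effect of large oncosomes on gene expression was first read from the rows with checked names. Of 517 genes, 4 rose and 4 fell after large oncosomes (limma, adjusted p under 0.05), and 68 had an unadjusted p under 0.05. CLDN11, encoding a claudin of tight junctions (chromosome 3, 170136653 to 170152479), fell from 141 ± 11.8 to 71.8 ± 10.8 FPKM (SD, n = 2 in each group), a log2 change of -0.97 with a standard error of 0.12 and an adjusted p of 0.00468 (limma). PARL, encoding a rhomboid protease of the inner mitochondrial membrane (chromosome 3, 183547173 to 183602693), fell from 19.7 ± 0.913 to 10.0 ± 0.0814 FPKM (SD, n = 2), a log2 change of -0.91 with a standard error of 0.10 and an adjusted p of 0.00146 (limma). SH2D5, encoding a protein with an SH2 domain (chromosome 1, 21046225 to 21059133), rose from 8.59 ± 0.774 to 16.0 ± 2.73 FPKM (SD, n = 2), a log2 change of 0.82 with a standard error of 0.13 and an adjusted p of 0.0179 (limma).

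The other called genes were less abundant. KCNT2, a potassium channel gene, rose from 2.24 to 4.05 FPKM (log2 change 0.64), NPAS1, a transcription factor gene, from 3.07 to 5.17 FPKM (0.60) and FLJ38109 from 3.63 to 5.92 FPKM (0.58). The zinc finger gene ZNF223 fell from 2.46 to 1.07 FPKM (-0.74) and the integrin subunit gene ITGA8 from 1.80 to 0.856 FPKM (-0.59). For these 5 genes the adjusted p in limma ran from 0.00707 to 0.0369, and for all 8 both large oncosome libraries lay beyond both controls. That held for 259 of the 517 genes (50.1%), 131 higher and 128 lower, against 33.3% by chance. Another 3 of the 517 rows changed by at least 1.04 on the log2 scale with the groups apart, and were not called. Genes next in order of p did not pass either. Toward higher values they were SVIL (log2 change 0.47, adjusted p = 0.0651, limma), ACY1 (0.50), EXOSC4 (0.47), SLC27A4 (0.45), DNLZ (0.40) and NCLN (0.50). Toward lower values they were TUSC3 (-0.48, adjusted p = 0.0573, limma), RAB8B (-0.53), TGFBR3, encoding the TGF-beta co-receptor betaglycan (-0.49), BBS10 (-0.39), LENG1 (-0.38) and IGF2BP2 (-0.34). The set of called genes depended on single choices: no gene was called with 3 neighbours in the name check (189 rows, 30 at an unadjusted p under 0.05, limma), without the robust option (66), without a filter on low values (79) or with a minimum change of 1.5-fold (2), 1 rose and none fell without control 1, none rose and 1 fell without control 2, 24 rose and 16 fell without large oncosome library 1, and 9 rose and 6 fell without large oncosome library 2. FLJ38109 and ITGA8 did not pass with quantile normalization (adjusted p = 0.0652 and 0.0542, limma) or with median centring. In simulated data 91.3% to 94.5% of rows passing the name check held their own values. There each library was displaced separately, so this share does not cover a misplacement shared by both large oncosome libraries.

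**Figure D3:**
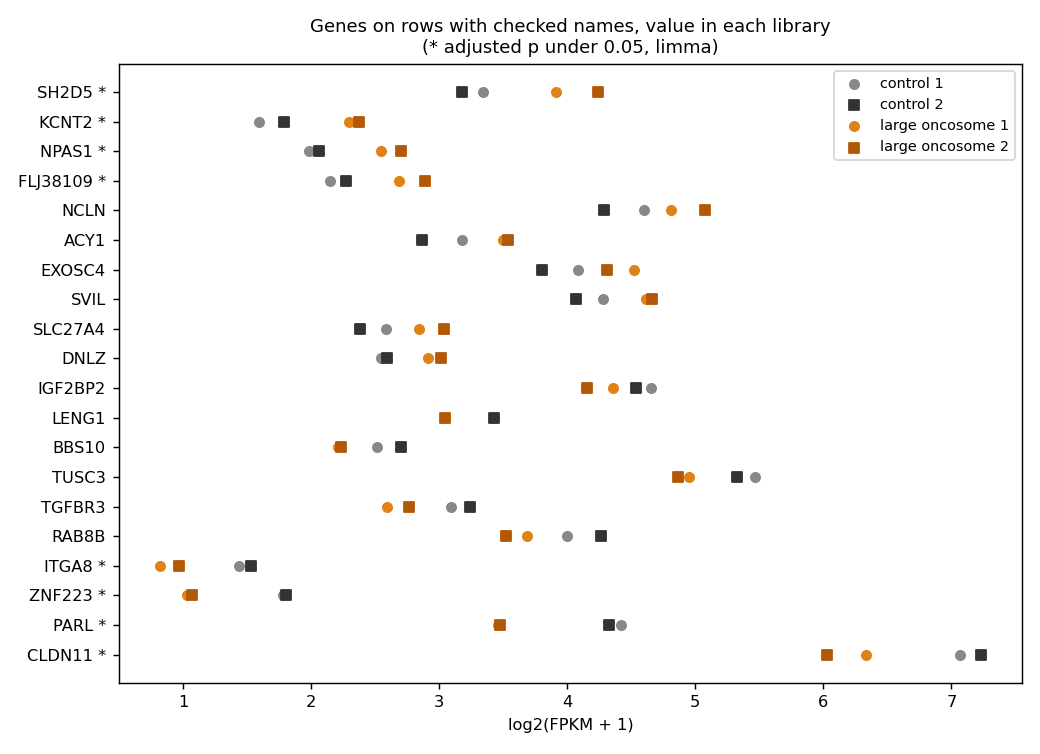
The 20 genes with the smallest p among rows with checked names, 10 in each direction, are shown with their value in each of the 4 libraries as log2(FPKM + 1), in order of their log2 change. In the 8 genes with an asterisk, which passed the test, both large oncosome libraries lie beyond both controls. CLDN11, at the bottom, averaged 141 FPKM in the controls and 71.8 FPKM after large oncosomes.

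Few members of the fixed lists were on rows with checked names. Of 14 tested members reported none was called by limma over all 517 rows, and 3 had an unadjusted p under 0.05. Of 4 MYC target and ribosome biogenesis genes, GNL3 had a log2 change of -0.04, AIMP2 of 0.05, RABEPK of 0.04 and SLC19A1 of -0.09. In the immediate early and ERK feedback list, DUSP6, a phosphatase gene that ERK signalling induces, stood at 27.4 ± 4.21 and 34.9 ± 0.276 FPKM (SD, n = 2; log2 change 0.35, adjusted p = 0.235, limma), PHLDA1 had a log2 change of 0.16 and KLF6 of -0.05. Adjusted over the list alone, 1 of these 3 genes (DUSP6) passed and none of the 4 MYC target genes did. Lists with 1 tested member leave nothing to adjust. TIMP3 (log2 change -0.26, unadjusted p = 0.0450, limma) and ENO2 (-0.31, unadjusted p = 0.0362, limma) were such members, and 68 of all 517 checked rows also had an unadjusted p under 0.05. The only tested members of 5 further lists had an unadjusted p of 0.05 or more (limma). Their log2 changes were 0.02 for DDX58 (interferon), 0.01 for FADS2 (lipid synthesis), 0.09 for TRIB3 (amino acid stress), 0.18 for SLC7A11 (NRF2) and -0.20 for RPL35 (ribosomal).

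For some abundant genes the highest value of their stretch of rows was taken, whichever row it stood on. Among 15 such maxima, 2 were lower and 0 higher after large oncosomes (limma, adjusted p under 0.05), and 5 had an unadjusted p under 0.05. For 14 of the 15 genes the maximum stood on another row in at least 1 library, so it may belong to another gene. TGFBI is a matrix protein gene named for its induction by TGF-beta (chromosome 5, 135364584 to 135399507). The maximum taken for it was 888 ± 34.4 FPKM in the controls and 666 ± 17.6 FPKM after large oncosomes (SD, n = 2; log2 change -0.41, standard error 0.11, adjusted p = 0.00779, limma). It stood on the row named TGFBI in all 4 libraries, but that row did not pass the name check. The maximum taken for the ribosomal protein gene RPS15A was 774 ± 17.7 FPKM in the controls and 622 ± 23.7 FPKM after large oncosomes, where it stood on the row named CLEC19A in both libraries (SD, n = 2; log2 change -0.31, standard error 0.11, adjusted p = 0.0453, limma). TPT1 (-0.29) and RPL5 (-0.27) lay in the same direction without passing, and LGALS1 (0.26), MT2A (0.21), UCHL1 (0.16), TIMP1 (0.13), GAPDH (0.13), COL1A2 (0.05), VIM (-0.03), TMSB10 (-0.05), EEF1A1 (-0.10), TPM2 (-0.15) and ANXA5 (-0.19) did not pass. Neither call remained when any 1 of the 4 libraries was left out, where 1 to 6 genes had an unadjusted p under 0.05 (limma), with a minimum change of 1.5-fold (0 genes) or with a wider window, where neither gene was among the 10 kept, and RPS15A did not pass with median centring (adjusted p = 0.0572, limma). With a narrower window, among 29 genes, the maxima taken for TGFBI and B2M were lower and those for RPS2 and IGFBP7 higher at an adjusted p under 0.05, while RPS15A did not pass (adjusted p = 0.131, limma).

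**Figure D4:**
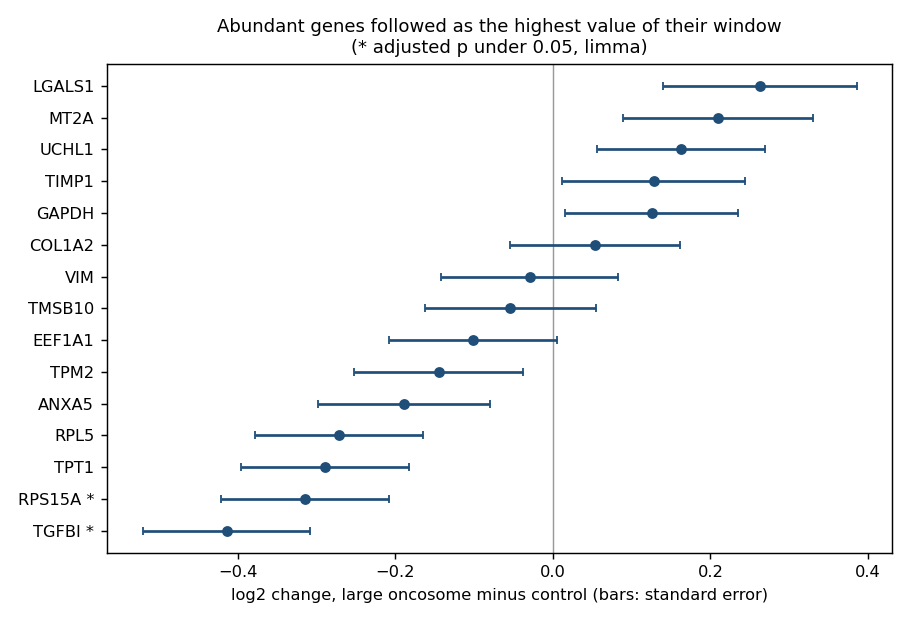
Points give the log2 change, large oncosome minus control, of the highest value in the stretch of rows around each of 15 abundant genes, with bars of 1 standard error from limma and 2 libraries in each group. Only the maxima taken for TGFBI (-0.41) and RPS15A (-0.31), marked with asterisks, passed the test.

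The genes named in advance were not on rows with checked names, and only their control 1 level can be tied to the gene: 15.7 FPKM for MYC, 51.9 for AKT1, 63.8 for ACTA2, encoding smooth muscle actin, 4.84 for IL6 and 154 for THBS1, with MMP9 listed at 0. The rows bearing their names held 0.0670, 47.5, 61.3, 8.70, 0.119 and 4.78 FPKM in control 2 in the order MYC, AKT1, ACTA2, IL6, THBS1 and MMP9. In the large oncosome libraries the MYC row held 0.0244 and 17.0 FPKM, the AKT1 row 0.129 and 15.1, the ACTA2 row 5.94 and 7.35, the THBS1 row 0.0317 and 23.8, the IL6 row 0.0951 and 0, and the MMP9 row 0.00957 and 0. No change of these genes is read from the rows.

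The test fixed in advance, over all 13392 tested rows as deposited, called 377 rows higher and 366 lower after large oncosomes (limma, adjusted p under 0.05), with a median size of 3.38 on the log2 scale among them. These are calls on rows, not on genes. The row named RPS15A held 762 and 787 FPKM in the controls and 6.77 and 7.18 FPKM in the large oncosome libraries, while the row named CLEC19A, 4 rows away, held 0 in both controls and 606 and 639 FPKM in the large oncosome libraries, the values taken above as the maximum of RPS15A's stretch. Rows named BTF3, CD151, CTSZ, RPN1 and RPL14 were among the 10 largest falls, each with over 100 FPKM in both controls and less than 1 FPKM after large oncosomes, and rows named RAD51D, FGL2, KIF27 and KLHDC1 among the 10 largest rises. No call was made by limma when any 1 of the 4 libraries was left out (1993 to 2414 rows at an unadjusted p under 0.05) or when rows with low values were kept (1624 rows).

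Over the same rows, camera called 4 of 23 lists, all toward lower values: fibroblast identity (16 rows), p53 targets (19), collagen and matrix (27) and cytosolic ribosomal proteins (42), each with an adjusted p of 0.0351. This direction cannot be read as a response. Control 1, a control, was the only library taken to follow the names, and the medians of these lists in it were 44.4, 21.5, 144 and 669 FPKM. Values displaced in the large oncosome libraries would lower such lists there whether or not the genes changed. With an estimated correlation camera called no list (0 at an unadjusted p under 0.05), and the adjusted p was 0.808 for each of these 4. The MYC target list (59 rows) had an adjusted p of 0.645 and the immediate early list (23 rows) of 0.872, by camera. These are tests on rows whose names were not checked, and the calls depended on single libraries: none was made without control 1 or without large oncosome library 2, 10 without control 2 and 1 without large oncosome library 1.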

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

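The checks of row names and windows were chosen after seeing the data, the other alternatives before. Over all rows as deposited, the counts of 377 higher and 366 lower became 0 and 0 when any 1 library was left out, with the replicate block and without a filter on low values, and 4 and 4 on rows with checked names only. On those checked rows, the counts of 4 and 4 ran from 0 to 24 higher and from 0 to 16 lower when 1 library was left out. They were 0 and 0 with the replicate block, without a filter, without the robust option, with a minimum change of 1.5-fold and with 3 neighbours, and 7 and 11 with 1 neighbour. In limma, the replicate block left 1268 rows as deposited and 40 checked rows at an unadjusted p under 0.05. Libraries with the same number did not deviate together (r = -0.06 over 517 checked rows), so the numbers are not read as pairs. A group left with 1 library is assumed to vary like the other.

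Among abundant genes, the 2 lower calls became 0 when any library was left out, with the replicate block, with a minimum change of 1.5-fold and with a wider window, and 1 with median centring; the 0 higher calls became 2 with a narrower window. The 4 list calls ran from 0 to 10 with 1 library left out, became 0 with an estimated correlation and 0 with fry, and were 4 with the replicate block.

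Signs changed for values that had not passed the test. With 1 library left out, log2 changes ran from -0.22 to 0.036 for SLC19A1, -0.023 to 0.064 for DDX58, -0.10 to 0.13 for FADS2, -0.10 to 0.28 for TRIB3, -0.017 to 0.12 for COL1A2, -0.0091 to 0.43 for MT2A, -0.035 to 0.29 for TIMP1, -0.15 to 0.044 for TMSB10, -0.15 to 0.088 for VIM, -2.04 to 2.09 for the row named MYC and -4.94 to 2.18 for the row named THBS1. FADS2 was at -0.0079 with quantile normalization, and the MYC row at -0.0043 with it and -0.15 with a pseudocount of 0.1. The cause of these moves was not tested, except that leaving out a library leaves fewer samples. Count-based tests were not run because the values are FPKM, and normalization by quantiles, the filters and the robust option were not applied to the abundant genes. Depth was estimated for control 1 only, and what it limits was not assessed.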

Other observations

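All tests in this part were chosen after the results were seen.

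Values in 3 libraries differ from control 1 at the same row. A response to large oncosomes is argued against as the cause, because 55.6% of rows at 10 FPKM or more were over 2-fold apart between the 2 controls. RNA of other cells, or degraded RNA, is argued against by control 2, in which 94.1% of the displaced abundant values were found within 100 rows, against 33.5% in distant stretches. A candidate explanation is that the values were written in another row order than the names, since even in the lowest library 76.5% of displaced values were found nearby, against at most 36.6% far away. How the order was lost was not tested.

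The 743 calls over all rows as deposited were weighed in the same way. A response to large oncosomes as the whole cause is argued against by the rows with checked names: 3 of 517 changed by at least the smallest size called (1.04 on the log2 scale) with the groups apart, against 743 called of the other 12875 rows (Fisher's exact test, two-sided, p = 8.95e-10). The 2 criteria differ: by size and separation alone, 2977 of the other rows (23.1%) changed. Neighbouring rows are not independent, so the p of Fisher's exact test is only descriptive. Whether row order accounts for the calls stays open: of 77 called rows at 100 FPKM or more in the higher group, 71.4% had that value on a nearby row in both libraries of the other group, against 49.9% on average and 54.5% at most in distant stretches, short of the 1.5 times set as the bound. Simulated libraries with rows displaced separately in each gave 0, 423 and 709 calls on unchanged rows in 3 simulations. The 2 other splits of the 4 libraries into pairs gave 0 calls each by limma, with 1086 and 1121 rows at an unadjusted p under 0.05 against 1384.

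For the 8 calls on rows with checked names, PARL, CLDN11, ZNF223, ITGA8, SH2D5, KCNT2, NPAS1 and FLJ38109, a misplacement shared by both large oncosome libraries and a response to large oncosomes cannot be told apart. A misplacement would leave the control level on another row nearby. Such a row was found in both large oncosome libraries for 7 of the 8 genes. The same search in distant stretches also gave 7 on average, so that it decides nothing. For CLDN11, the exception, such a row was found in large oncosome library 2 but not in library 1. Only 2 of 5 distant stretches held one for CLDN11 in both libraries, so its lack nearby does not set this gene apart. A row nearby that could have traded values with the called row in both large oncosome libraries was found for PARL alone, which also had one in 1 of 5 distant stretches. The labelled split gave 68 checked rows with an unadjusted p under 0.05 and the other splits 11 and 6, but 3 splits are too few for a share under 0.05. It is a hypothesis that CLDN11 transcripts may be lower in these fibroblasts 6 h after large oncosomes, which a table of values written in the order of its names would test.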
